A study of Equus caballus with 15 samples.

How the data were processed

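The study sampled the superficial digital flexor muscle of the front limb with its attached tendon in 5 euthanized horses, 4 mares and 1 gelding. Per the labels' protocols, a biopsy punch of 4 mm was frozen and cryosectioned along the plane of the tendon, and about 200 micrometres each were collected as muscle, as tendon and as a sample of the myotendinous junction (MTJ) with muscle and tendon around it. RNA was extracted with a phenol-based reagent, mRNA was enriched with oligo-dT or by removal of ribosomal RNA, cDNA was primed with random hexamers, and libraries were read on a DNBseq sequencer. Each library was taken to be 1 tissue of 1 horse, from the tissue label and the horse number, giving 3 groups of 5. The labels also give a training state, but for horse 14 the muscle label differs from the MTJ and tendon labels, so training was not compared.

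The authors deposited a table of read counts per gene and library with NCBI gene numbers, symbols and chromosomes. The counts are whole numbers and are not normalized, per the file headers and the values. Genome build EquCab3.0 and DESeq2 1.26.0 are named in the submitters' processing notes. The aligner, the counting program and the strand setting are not given in the sources used here. Without strand, reads of overlapping genes cannot be told apart, and reads of near-identical genes such as ACTC1, MYH8 and ribosomal proteins could be split between copies. The same deposited table gives a Length for each gene, a whole number that the file headers do not explain, and it was not used. The authors deposited a second table with the log2 change of each MTJ section relative to a value predicted from muscle and tendon, per horse and as a mean. It carries an FDR, a p-value the authors adjusted over genes. The deposited adjusted p-values equal those of a one-sided one-sample test on the 5 deposited values with Benjamini-Hochberg adjustment, within 3.39e-15, as checked on the table. The authors also deposited lists of 219 muscle and 322 tendon reference genes with log2 fold changes and adjusted p-values. One entry of the tendon list is a number in place of a symbol.

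The table has 30297 genes, and 15343 were tested after edgeR's filter on low counts removed 14954. Library totals ran from 15304218 to 19295339 counts, and TMM scaling factors (trimmed mean of M values) from 0.671 to 1.88. CPM, counts scaled to a common library total, were computed with these factors. Of 549 listed symbols 4 matched no gene, and 86 symbols occur more than once in the table. No 2 libraries held identical counts, and the lowest chi-square per gene between libraries of a tissue was 18.6. After removing tissue means, libraries of the same horse correlated with r of 0.136 to 0.490 over 15 pairs, against -0.277 to 0.117 between horses, and 15 of 15 libraries correlated best with their own horse. As the horse number marks 1 animal, horse was kept as a block in each fit. Without the block (no replicate block) 650 genes were higher and 13 lower in the MTJ than in muscle.

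Pairwise comparisons used edgeR 4.0.16 in R 4.3.3, with quasi-likelihood tests on all 15 libraries so that the tissues shared 1 estimate of the spread, tissue and horse as terms, and Benjamini-Hochberg adjustment. The spread among tendon libraries thus also entered the test of MTJ against muscle, and the number of calls there changed when tendon libraries were left out. A gene was called at an adjusted p under 0.05. A gene was outside both tissues when the larger of the p-values of MTJ against muscle and against tendon, in the same direction, passed after adjustment. The share of muscle-type RNA in an MTJ section was the median ratio of MTJ to muscle CPM over the muscle reference genes of the same horse, and the share of tendon-type RNA was likewise the median over the tendon reference genes. Each MTJ library was compared with the sum of its horse's muscle and tendon CPM at these shares, as log2 ratios with 0.5 CPM added to both sides, and the 5 ratios of each gene were tested with limma 3.58.1. These log2 ratios understate the change of genes with low counts. Fixed gene lists of cell types, complexes and pathways, 31 in number, were tested with camera at a preset correlation of 0.01 where at least 5 genes were measured, which held for 30 lists. They were also tested with an estimated correlation and with fry.

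Named genes were chosen by a rule fixed before the data were examined. It took the 10 genes higher and the 10 lower with the largest log2 fold change among those called, with a mean of at least 5 CPM over 15 libraries, the same direction in 5 horses and a gene symbol. Against the mixture it took up to 15 above and 10 below by log2 ratio. It also took every measured MTJ myonuclear marker and up to 4 called members of each list, and the text names a subset. XIST was not used here.

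The tests were run on simulated counts with known changes, some up and some down, at the totals of the real libraries. For the pairwise tests and the test against both tissues, every tissue was drawn from the muscle means. For the mixture the muscle and tendon means were used. MTJ against muscle recovered 64 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, with 5 unchanged genes called. Muscle against tendon recovered 67 and 93, with 1 unchanged gene called. The test against both tissues recovered 59 and 88, with 2. Against the mixture 58 of 97 genes set 2-fold and 90 of 96 set 4-fold were recovered, with 31 unchanged genes called, and shares set to 0.8 and 0.15 were estimated at 0.843 and 0.191. Solving both shares together gave 0.828 and 0.154, and this was added as an alternative after the simulation. DESeq2 1.42.0 on MTJ against muscle recovered 76 and 94 with 25 unchanged genes called.

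Alternatives fixed in advance were other size factors, DESeq2, no filter and a stricter filter on low counts, no horse block, only the 10 libraries of the 2 tissues, other pseudocounts, shares from other reference lists, and each horse left out. Added after seeing the data were the shares solved jointly and fits without the tendon libraries of horses 14, 16 and 17, whose sections held muscle transcripts. Against the mixture, which needs all tissues of a horse, this last setting kept horses 18 and 20 alone. It then tested 2 ratios per gene, so calls can be lost there through fewer horses.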

Results

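RNA was sequenced from cryosections of the superficial digital flexor muscle and its tendon of 5 euthanized horses, 4 mares and 1 gelding, identified here by their numbers 14, 16, 17, 18 and 20. From each horse a biopsy punch of muscle with its attached tendon was frozen and cut along the plane of the tendon. About 200 micrometres of sections were collected as muscle, as tendon, and as another sample that holds the myotendinous junction (MTJ), where muscle fibres end on tendon collagen, with some of both tissues. The design therefore gave 15 libraries, 5 per tissue, with all 3 tissues from every horse. Total counts were 17115884 to 19295339 per muscle library, 17160894 to 18659381 per MTJ library and 15304218 to 17048957 per tendon library. The 10 most abundant genes took 29.5% of the counts in muscle, 26.1% in the MTJ and 14.8% in tendon, as means of 5 libraries. Values are given in CPM (counts scaled to a common library total) as mean ± SD over 5 libraries, and fold changes on the log2 scale with their standard errors (SE).

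Muscle and tendon sections were first compared to learn which transcripts separate the tissues on either side of the junction. Of 15343 genes tested, 5301 were higher in muscle and 5917 were higher in tendon, of which 3303 and 3928 differed at least 2-fold (edgeR quasi-likelihood test with horse as a block, adjusted p under 0.05). Genes higher in tendon included matrix genes and genes with other roles. COMP, which encodes cartilage oligomeric matrix protein, stood at 8562 ± 2006 CPM in tendon and 2.76 ± 1.03 CPM in muscle, a log2 change of -11.72 ± 0.71 (SE, muscle over tendon, adjusted p = 2.49e-08). CILP2, a matrix protein of cartilage-like tissue, had a log2 change of -10.46 ± 0.84 and ANGPTL7, a secreted angiopoietin-like protein, one of -10.20 ± 0.90. LOX, the enzyme that cross-links collagen, reached 1326 ± 434 CPM in tendon against 2.76 ± 1.58 CPM in muscle. MKX, a transcription factor of tendon cells, reached 38.5 ± 10.9 CPM against 0.123 ± 0.117 CPM, and PRELP, a small leucine-rich proteoglycan, 2303 ± 674 CPM against 26.9 ± 3.72 CPM.

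Genes higher in muscle included contractile and metabolic genes and genes with other roles. CA3, the carbonic anhydrase of slow muscle fibres, stood at 10739 ± 1405 CPM in muscle and 739 ± 762 CPM in tendon, a log2 change of 4.32 ± 1.01 (SE, adjusted p = 0.00212, edgeR). MYOM2, an M-band protein, changed by 4.68 ± 0.98, PYGM, muscle glycogen phosphorylase, by 4.17 ± 0.86, and CKMT2, the sarcomeric mitochondrial creatine kinase, by 4.24 ± 0.75. CHRNA1, the alpha subunit of the acetylcholine receptor, changed by 4.74 ± 0.84. Every gene named for this comparison so far had the same direction in 5 of 5 horses. The naming rule required this of genes picked by size of change, so it is no added evidence. The level of muscle transcripts in the tendon sections differed widely between horses. For the median gene of the muscle reference list it was 13.7, 17.6 and 11.7% of the level in the same horse's muscle section in horses 14, 16 and 17, and 0.328 and 2.56% in horses 18 and 20. These levels are in CPM with TMM factors. In CPM without the factors they were 31.8, 37.0 and 27.8% in horses 14, 16 and 17, and 0.843 and 6.23% in horses 18 and 20. Without the tendon libraries of horses 14, 16 and 17, a setting chosen after the data were seen, the log2 change of CA3 was 8.47, that of MYOM2 7.79, that of PYGM 7.29 and that of CHRNA1 7.36, and CKMT2 stood at 6.73.

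Among the gene lists fixed in advance, the muscle lists were higher in muscle nearly throughout. This held for 28 of 28 measured genes of oxidative phosphorylation, 16 of 16 of glycolysis and glycogen, 15 of 15 of excitation-contraction coupling, 13 of 13 of the fast-fibre sarcomere and 11 of 12 of the slow-fibre sarcomere. Examples were NDUFA4, a subunit of cytochrome c oxidase, at 3.57 ± 0.41, ENO3, muscle enolase, at 3.68 ± 0.74, CASQ1, the calcium store of fast fibres, at 4.03 ± 0.89, and TNNI2, fast troponin I, at 3.98 ± 0.75. Without the 3 tendon libraries with the most muscle RNA these log2 changes were 4.92, 6.07, 7.12 and 6.43. Counts adjusted over the list alone were the same. Of the fast-fibre list 11 genes and of the slow-fibre list 10 are also reference genes that the study chose on these samples, so their direction is not independent evidence. With the preset correlation these lists had camera adjusted p of 4.28e-14, 3.89e-06, 0.00241, 0.00495 and 0.0113, and with an estimated correlation adjusted p of 0.406, 0.407, 0.701, 0.701 and 0.701. Of 11 developmental myosin and myogenic genes 9 were higher in muscle, MYH8 or perinatal myosin among them at 3.34 ± 0.44, and of 14 genes of the neuromuscular junction 11 were higher and 1 lower (adjusted p = 0.0129 and 0.0367). For these the adjusted p was 0.701 and 0.578 with an estimated correlation.

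Tendon sections held more of the connective tissue lists. Of 19 tenocyte markers 18 were higher in tendon, of 13 fibrillar and associated collagens 12, and of 11 fibro-adipogenic progenitor markers 11. Of 29 genes of TGF-beta and BMP signalling 21 were higher in tendon and 1 in muscle, of 25 matrix remodelling genes 18 and 2, of 23 YAP/TAZ target genes 17 and 4, and of 19 basement membrane genes 12 and 3. COL12A1, a collagen of the fibril surface, had a log2 change of -6.29 ± 0.40, LTBP2, a binding protein of microfibrils, -6.36 ± 0.46, TIMP2, an inhibitor of metalloproteinases, -5.39 ± 0.32, and CCN2, a YAP/TAZ target also called connective tissue growth factor, -6.19 ± 0.40. Of 13 macrophage and monocyte markers 12 were higher in tendon, among them the mannose receptor MRC1 at -2.40 ± 0.29, and of 26 Hedgehog and Wnt genes 13 were higher in tendon and 2 in muscle. Counts adjusted over the list alone were the same for each. With an estimated correlation adjusted p was 0.294, 0.156, 0.156, 0.0537, 0.156, 0.294, 0.578, 0.578 and 0.405 for these 9 lists in the order given, against at most 0.0172 with the preset correlation. In all 16 of 30 lists were called with the preset correlation and 0 with an estimated one, while fry, which asks whether a list's genes move one way, called 23. The ribosomal protein list was not called (adjusted p = 0.475), with 13 members higher in tendon and 4 in muscle. RPL3 stood at 1227 ± 47.2 CPM in tendon and 182 ± 32.7 CPM in muscle. Ribosomal protein genes have many processed copies between which reads can be split.

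The MTJ section was then set against the adjacent muscle, to find transcripts that the junction adds to muscle. In the MTJ 947 genes were higher and 85 lower than in muscle, 616 and 11 of them at least 2-fold (edgeR, adjusted p under 0.05). Genes that rose included tendon matrix genes and genes with other roles. COMP rose from 2.76 ± 1.03 to 514 ± 425 CPM, a log2 change of 7.35 ± 0.61 (SE, adjusted p = 2.74e-05), and LOX rose by 4.71 ± 0.57. COL22A1, which encodes a collagen of tissue junctions (chromosome 9), rose from 0.278 ± 0.0964 to 20.9 ± 6.71 CPM, a log2 change of 6.37 ± 0.92 (adjusted p = 0.00300). NEFM, the medium neurofilament chain, rose by 6.52 ± 1.00 to 52.8 ± 25.3 CPM, and LCT, which encodes intestinal lactase, by 6.32 ± 0.94 to 18.1 ± 8.33 CPM. SORBS2, an adaptor protein of the actin cytoskeleton and Z-discs, rose by 2.92 ± 0.40, and FBLN7, a fibulin of the matrix, by 5.03 ± 0.70. These genes had the same direction in 5 of 5 horses, which the naming rule required of genes picked by size of change.

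Fewer genes fell in the fit of 15 libraries, whereas with only the 10 muscle and MTJ libraries 1488 were higher and 1450 lower. The largest falls among the named genes were those of CHRNE, ETV4 and MAP2K1. CHRNE, the adult epsilon subunit of the acetylcholine receptor of the endplate, the site of nerve contact on a fibre, fell from 24.9 ± 20.5 CPM in muscle to 3.23 ± 1.20 CPM in the MTJ, a log2 change of -2.74 ± 0.47 (SE, adjusted p = 0.00570, edgeR). ETV4, an ETS transcription factor, had a log2 change of -3.07 ± 0.63, and MAP2K1, the kinase MEK1 of the ERK pathway, one of -2.95 ± 0.53 from 150.3 ± 123 CPM in muscle. The muscle level of these genes varied between horses, and MAP2K1 stood at 113, 264, 295, 21.7 and 57.3 CPM in the muscle sections of horses 14, 16, 17, 18 and 20. Without horse 14 the adjusted p was 0.0882 for ETV4 and 0.0542 for MAP2K1, and without horse 16 0.0732 and 0.0592, while CHRNE kept its call in each of the 5 fits that left out a horse. IMMP2L, a peptidase of the inner mitochondrial membrane, fell by 0.65 ± 0.09 on the log2 scale, and GPC4, a cell-surface proteoglycan, by 0.99 ± 0.20. TFRC, the transferrin receptor, fell by 0.96 ± 0.19 and was not called without horse 16 (adjusted p = 0.0509) or without the horse block (0.404).

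**Figure D1:**
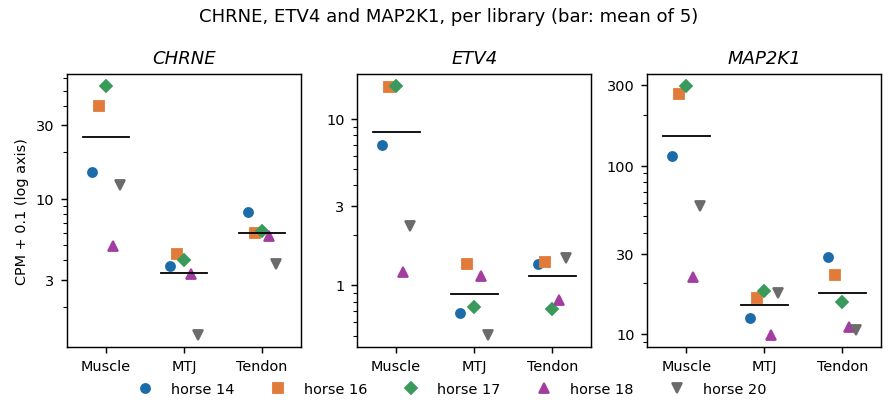
CPM plus 0.1 (log axis) of CHRNE, ETV4 and MAP2K1 in each of the 15 libraries, by tissue, with a symbol per horse and a bar at the mean of 5. MAP2K1 stood at 150.3 ± 123 CPM in muscle sections and 14.7 ± 3.55 CPM in MTJ sections.

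Of the lists, 11 were called up and 3 down in the MTJ against muscle with the preset correlation, and 5 stayed called with an estimated correlation. Those 5 were the tenocyte markers (15 of 19 rose, 17 adjusted over the list alone; adjusted p = 0.0337 with an estimated correlation), fibrillar and associated collagens (10 of 13, 11 alone; 0.0337), fibro-adipogenic progenitor markers (5 of 11, 9 alone; 0.0337), matrix remodelling enzymes (8 of 25, 10 alone; 0.0403) and TGF-beta and BMP signalling (8 of 29, 12 alone; 0.0204). No member of these 5 fell. MKX rose by 4.86 ± 0.55, COL12A1 by 2.81 ± 0.36, TIMP2 by 2.09 ± 0.28, LTBP2 by 3.60 ± 0.43 and PI16, a marker of fibroblast progenitors, by 1.09 ± 0.20. The MTJ section holds some tendon by design, tendon reference genes stood at 15.9 ± 5.16% of their tendon level in the MTJ sections (SD, n = 5), and the tenocyte list shares 11 of its 19 genes with the tendon reference genes that the study chose on these samples. Without the horse block the adjusted p of PI16 was 0.0586.

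Of 13 macrophage and monocyte markers 8 rose from muscle to MTJ and 12 did so adjusted over the list alone (camera adjusted p = 9.25e-12; adjusted p = 0.123 with an estimated correlation). MRC1 rose by 1.40 ± 0.29 (adjusted p = 0.0895 without the horse block) and the scavenger receptor MSR1 by 2.31 ± 0.52, and their calls were lost without horse 18 (adjusted p = 0.0515) and without horse 20 (0.0972) respectively. Of 12 MTJ myonuclear markers, genes known from nuclei of fibre ends in other species, 6 rose, 7 did so adjusted over the list alone and 0 fell (adjusted p = 5.03e-09; 0.144 with an estimated correlation). The 6 were COL22A1, SORBS2, NAV3 (2.64 ± 0.23), TIGD4 (3.47 ± 0.58), COL24A1 (2.45 ± 0.39) and MAML2 (0.71 ± 0.14). YAP/TAZ target genes (7 of 23 rose, 9 alone), Hedgehog and Wnt genes (5 of 26, 6 alone), basement membrane genes (5 of 19, 6 alone) and synovial lining markers (2 of 8) were also called up, with adjusted p of 0.144, 0.144, 0.399 and 0.141 with an estimated correlation. The lists called down were oxidative phosphorylation, in which 0 of 28 genes passed alone or over all genes (median log2 change -0.38), glycolysis and glycogen (0 of 16, median -0.25) and the neuromuscular junction (2 of 14 fell, CHRNE and ETV4). Their adjusted p was 0.725, 0.867 and 0.361 with an estimated correlation. Muscle reference genes stood at 77.6 ± 5.68% of their muscle level in the MTJ sections (SD, n = 5), and the log2 of the mean share was -0.37. Against a mixture of each horse's muscle and tendon, described below, the medians of these lists were -0.02, 0.07 and -0.21. Less muscle RNA in the MTJ section would thus lower the first list by about as much as seen. Markers of other cell types were not called between MTJ and muscle: endothelial (0 of 15 genes; adjusted p = 0.423), pericyte and smooth muscle (1 of 11; 0.724), lymphocyte (0 of 11; 0.880), adipocyte (1 of 9; 0.850), Schwann cell and nerve (0 of 12; 0.850) and satellite cell (0 of 9; 0.825). Nor were the immediate early and heat shock genes (2 of 25; 0.916) or the cell cycle genes (0 of 15; 0.724).

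The number of genes called between MTJ and muscle differed between fits. Of the 1032 calls of the fit of 15 libraries, 926 were tested again with only the 10 muscle and MTJ libraries, where the filter passed 13564 genes, and 921 were kept. Without the horse block 650 were higher and 13 lower, and with DESeq2 1155 and 285. Without the tendon libraries of horses 14, 16 and 17 they were 1238 and 623. Leaving out horse 14 gave 576 higher and 18 lower, horse 16 741 and 31, horse 17 683 and 18, horse 18 659 and 40, and horse 20 600 and 40.

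The MTJ section was also set against tendon, its other neighbour. In the MTJ 5024 genes were higher and 5275 lower than in tendon, 2921 and 2972 of them at least 2-fold (edgeR, adjusted p under 0.05). CHRNG, the embryonic gamma subunit of the acetylcholine receptor, stood at 19.2 ± 20.9 CPM in the MTJ and 0.489 ± 0.466 CPM in tendon, a log2 change of 4.82 ± 1.18 (SE, adjusted p = 0.00517). ACTC1, the cardiac actin of developing muscle, stood at 546 ± 534 and 88.6 ± 121 CPM, a change of 3.88 ± 0.97. MYBPC1, slow myosin-binding protein C, changed by 3.67 ± 0.87 and MYL2, the slow regulatory light chain, by 3.47 ± 0.91. On the other side PLA2G2A, a secreted phospholipase, stood at 0.523 ± 0.345 CPM in the MTJ and 39.2 ± 42.4 CPM in tendon, and EMILIN1, an elastin-associated glycoprotein, changed by -4.50 ± 0.49. TSKU, a small leucine-rich protein, changed by -4.30 ± 0.47, LOX by -4.30 ± 0.54 and COMP by -4.37 ± 0.54. All had the same direction in 5 of 5 horses, a condition of the naming rule for genes picked by size of change. Reads of ACTC1 can be split with its near-identical paralog in skeletal muscle. Without the tendon libraries of horses 14, 16 and 17 the adjusted p of CHRNG was 0.110, and the log2 change of MYBPC1 was 6.76, that of MYL2 6.65 and that of ACTC1 5.88. Without the horse block the adjusted p of ACTC1 was 0.0929.

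All 28 genes of oxidative phosphorylation, 16 of glycolysis, 15 of excitation-contraction coupling, 13 of the fast-fibre and 12 of the slow-fibre sarcomere and 11 developmental and myogenic genes were higher in the MTJ than in tendon, with the same counts adjusted over the list alone. COX6A2, the muscle form of a cytochrome c oxidase subunit, changed by 3.64 ± 0.83, PYGM by 3.79 ± 0.84 and MYL4, an atrial and embryonic light chain, by 3.36 ± 0.58. Without the tendon libraries of horses 14, 16 and 17 COX6A2 changed by 6.22 and PYGM by 6.92. Adjusted p for the 6 lists was at most 0.00522 with the preset correlation, and 0.366, 0.366, 0.643, 0.643, 0.643 and 0.643 with an estimated correlation. Lists called down were the tenocyte markers (17 of 19 lower, 1 higher), collagens (12 of 13 lower, 13 alone), matrix remodelling enzymes (15 of 25 lower, 2 higher), TGF-beta and BMP signalling (19 of 29 lower, 2 higher), YAP/TAZ targets (15 of 23 lower, 4 higher), fibro-adipogenic progenitor markers (10 of 11 lower) and basement membrane genes (11 of 19 lower, 4 higher). COL12A1 changed by -3.48 ± 0.34, the BMP target ID1 by -2.90 ± 0.29, CCN2 by -3.61 ± 0.36 and NID2, a basement membrane linker, by -2.48 ± 0.17. With an estimated correlation their adjusted p was 0.366, 0.358, 0.358, 0.137, 0.358, 0.358 and 0.643. With the preset correlation the basement membrane genes were close to the threshold (camera adjusted p = 0.0464). Of the 13 lists called against tendon, 12 kept their call without horse 14, 16 or 20 and without the horse block. COL22A1 was higher in the MTJ than in tendon by 1.90 ± 0.64 (adjusted p = 0.0251), in 4 of 5 horses. That call was lost without horse 14 (0.0522), 17 (0.108) or 20 (0.0776), without the horse block (0.102), with no filter (0.0586) and with the 10 libraries of the 2 tissues alone (0.0859). Without the tendon libraries of horses 14, 16 and 17, a setting chosen after the data were seen, COL22A1 kept its call (2.97, edgeR adjusted p = 0.0206).

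Genes outside the range of both neighbours were sought with a test that needs the MTJ to differ from muscle and from tendon in the same direction. With edgeR 0 genes were above both tissues and 0 below both after adjustment, while 100 and 80 had an unadjusted p under 0.05. Tissue labels were also exchanged within each horse. Of 100 such groupings, the real one included, 13 gave at least these 180 genes, and the others had a median of 17 and a highest count of 10107. The exchange took in all 3 tissues, so a grouping can give the MTJ label mostly to tendon libraries, which differ from both other tissues. Such groupings are no measure of chance for the MTJ. The 13 therefore do not decide whether 180 is more than chance would give. DESeq2 called 3 genes above both and 0 below. They were ME1, the cytosolic malic enzyme, at 5.60 ± 1.55, 11.7 ± 2.79 and 6.24 ± 2.32 CPM in muscle, MTJ and tendon, CD52, a surface glycoprotein of leukocytes, at 6.28 ± 1.37, 15.7 ± 3.34 and 4.28 ± 1.90 CPM, and HHIP, a Hedgehog-binding protein, at 0.325 ± 0.240, 4.91 ± 3.40 and 0.805 ± 0.835 CPM. Adjusted p in DESeq2 was 0.00186, 0.0292 and 0.0292. These 3 genes, and APOD below, were named after their values were seen. Without horse 18 edgeR called CD52 above both (adjusted p = 0.0152) and APOD, a secreted lipocalin, below both (adjusted p = 0.00333). In the MTJ section of that horse the median log2 ratio of 11 Schwann cell markers to the mixture was 1.93, against -1.35 to -0.0485 in the other 4, and nerve in that section was not modelled. On simulated counts of the same size this test found 88 of 100 genes changed 4-fold in the MTJ and 59 of 100 changed 2-fold, up or down. In that simulation muscle and tendon were drawn at the same level for every gene. The recovery therefore does not carry over to genes that differ between muscle and tendon, and does not bear on the count of 0.

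As the MTJ section holds muscle and tendon beside the junction, the amounts of muscle-type and tendon-type RNA in it were estimated from the authors' deposited lists of 219 muscle and 322 tendon reference genes. The MTJ sections held 77.6 ± 5.68% of the level of muscle genes and 15.9 ± 5.16% of the level of tendon genes found in the same horse's muscle and tendon sections (SD, n = 5). Per horse the muscle share was 80.6, 83.4, 75.7, 68.8 and 79.7% and the tendon share 13.7, 12.3, 24.5, 16.8 and 12.2% in horses 14, 16, 17, 18 and 20. These shares are ratios of CPM with TMM factors and not fractions of the RNA in a library. The factors were 0.671 to 0.747 in muscle, 0.761 to 0.929 in MTJ and 1.46 to 1.88 in tendon libraries. Shares in CPM without these factors were not computed. With lists fixed in advance in place of the deposited ones the tendon share was 25.8%. Muscle's own part of these genes was left out, which raises that share. The collagens among them had a median log2 change of only -2.41 between muscle and tendon. Tendon reference genes in the muscle sections reached 4.75 ± 1.27% of their tendon level. The reference genes had been chosen by the study on these samples, so their direction between the tissues is not independent evidence.

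**Figure D2:**
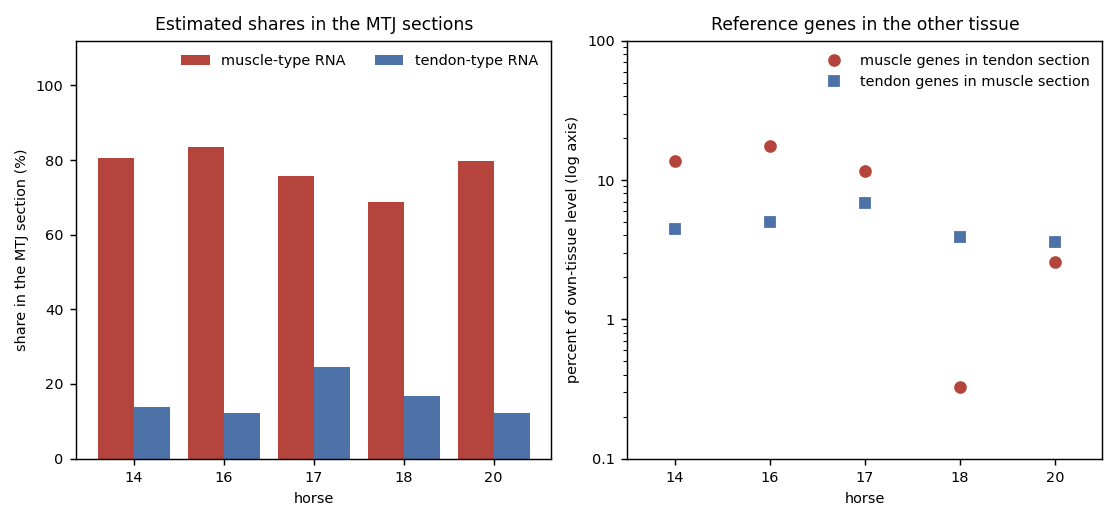
Left, estimated share (%) of muscle-type and tendon-type RNA in the MTJ section of each of the 5 horses, as ratios of CPM with TMM factors. Right (log axis), median level of muscle reference genes in the tendon section and of tendon reference genes in the muscle section, as a percentage of the level in the horse's own muscle or tendon section. In CPM with TMM factors, as drawn, muscle genes in tendon ran from 0.328% in horse 18 to 17.6% in horse 16.

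Each MTJ library was next compared with the mixture of its own horse's muscle and tendon libraries at these shares, which asks which transcripts the junction holds beyond its neighbours. Of 15343 genes 487 were above the mixture and 130 below, 103 and 29 of them at least 2-fold (limma on the 5 within-horse log2 ratios, adjusted p under 0.05). In the simulation of this test 31 unchanged genes were called beside 58 and 90 recovered ones, a larger part of the calls than 0.05. With shares solved jointly it was 16 beside 54 and 90, also a larger part. The calls against the mixture can thus hold more false ones than the threshold implies. NEFM had the highest ratio among the genes named by the rule, 3.80 ± 0.44 (SE, adjusted p = 0.0167). COL22A1 followed at 3.65 ± 0.23 (adjusted p = 1.06e-05) and LCT at 3.47 ± 0.39 (adjusted p = 0.00570). POSTN, a matrix protein of healing and loaded tissue, was above the mixture by 2.86 ± 0.39, at 33.6 ± 13.6 CPM in the MTJ against 3.86 ± 1.60 in muscle and 7.58 ± 6.51 in tendon. NCAM1, the neural cell adhesion molecule also made by satellite cells and denervated fibres, was above by 2.71 ± 0.36, at 149 ± 27.4 CPM against 22.8 ± 11.1 and 48.6 ± 53.4. FGF7, a fibroblast growth factor that acts on epithelia, was above by 2.49 ± 0.13, and ACTC1 by 2.32 ± 0.21. IGSF1, a membrane glycoprotein (chromosome X), was above by 2.85 ± 0.20, PPP2R2B, a regulatory subunit of protein phosphatase 2A, by 2.73 ± 0.32, and ALDH3B1, an aldehyde dehydrogenase, by 2.28 ± 0.13. All these ratios were above 0 in 5 of 5 horses, a condition of the naming rule for genes picked by size of ratio.

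**Figure D3:**
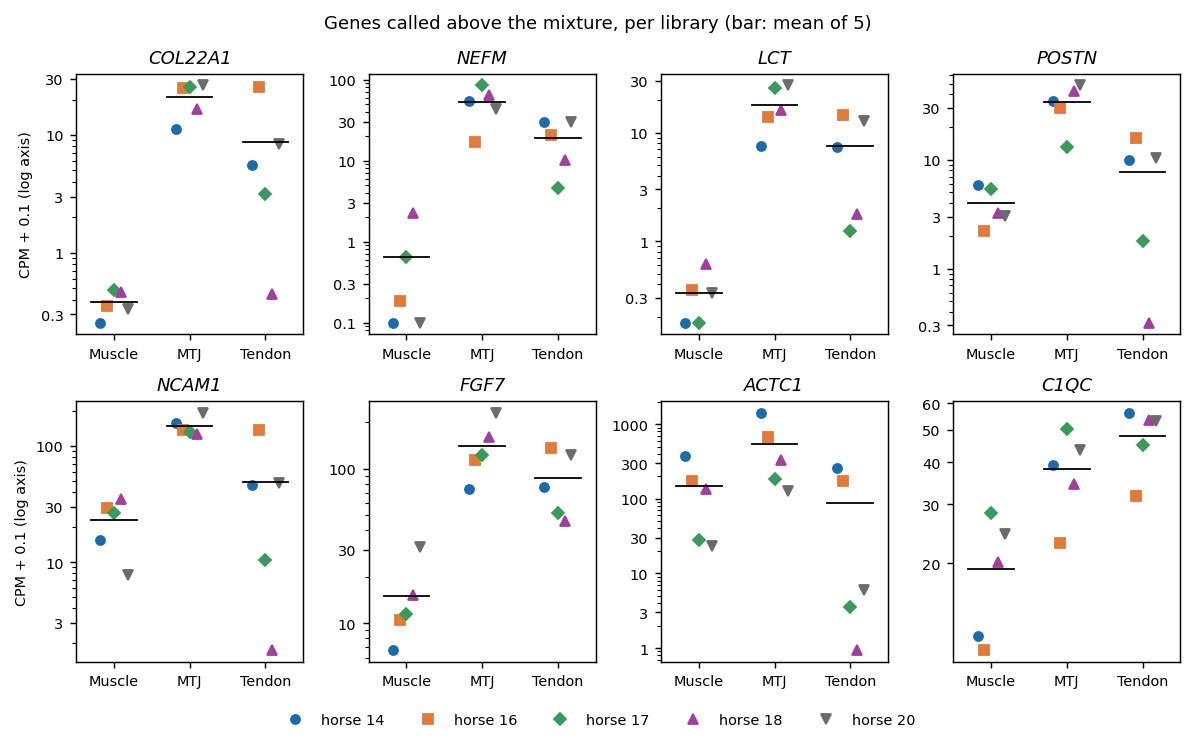
CPM plus 0.1 (log axis) of 8 genes called above the mixture in each of the 15 libraries, by tissue, with a symbol per horse and a bar at the mean of 5. COL22A1 averaged 20.9 ± 6.71 CPM in the MTJ, 0.278 ± 0.0964 in muscle. It was lower in tendon than in the MTJ in 4 of 5 horses, and the tendon library of horse 16 stood at 25.7 CPM.

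Several of these calls were lost when single horses were left out. Without horse 14 the adjusted p was 0.0795 for NEFM, 0.0780 for POSTN, 0.141 for NCAM1 and 0.109 for SORBS2, which was above the mixture by 2.35 ± 0.31. Without horse 16 it was 0.0795 for POSTN and 0.0544 for SORBS2, without horse 17 0.0976 for NCAM1 and 0.0783 for SORBS2, and without horse 18 0.0752 for NEFM and 0.120 for NCAM1. Without horse 20 it was 0.0835 for NEFM, 0.0801 for POSTN and 0.140 for SORBS2. Each log2 ratio stayed above 0. COL22A1, IGSF1, FGF7, ALDH3B1, CPEB1 (1.77 ± 0.15) and MNS1 (1.75 ± 0.18) kept their calls in all 5 of these fits. CPEB1 binds an element in the 3' untranslated region of mRNAs and regulates their tails, and MNS1 is a structural protein of cilia and flagella.

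Most genes below the mixture were higher in tendon than in muscle. RGS7, a regulator of G-protein signalling, had a log2 ratio of -1.74 ± 0.17 (SE, adjusted p = 4.76e-05, limma), SOD3, extracellular superoxide dismutase, -1.50 ± 0.17, CRABP1, a retinoic acid binding protein, -1.40 ± 0.17, and CHST3, a chondroitin sulfotransferase, -1.15 ± 0.16. COL12A1 had -0.83 ± 0.14. With 1 share per horse neither CHST3 (-0.65, adjusted p = 0.0646) nor COL12A1 (-0.24, adjusted p = 0.152) was called. With horses 18 and 20 alone the adjusted p was 0.109 and 0.0854. With no filter it was 0.0674 for CRABP1 and 0.144 for COL12A1. Of the 130 genes below the mixture 106 were higher in tendon than in muscle and 17 were higher in muscle, and 60 were tendon reference genes. Of all 15343 genes 5917 were higher in tendon and 5301 in muscle. In the simulation the tendon share came out at 0.191 where 0.15 was set, and a share set too high puts tendon genes below the mixture. With reference genes left out 65 genes were below, and with shares solved jointly 93. Of the 487 above it 218 were higher in tendon, 165 higher in muscle and 104 neither, and 274 had an MTJ mean above both tissue means.

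**Figure D4:**
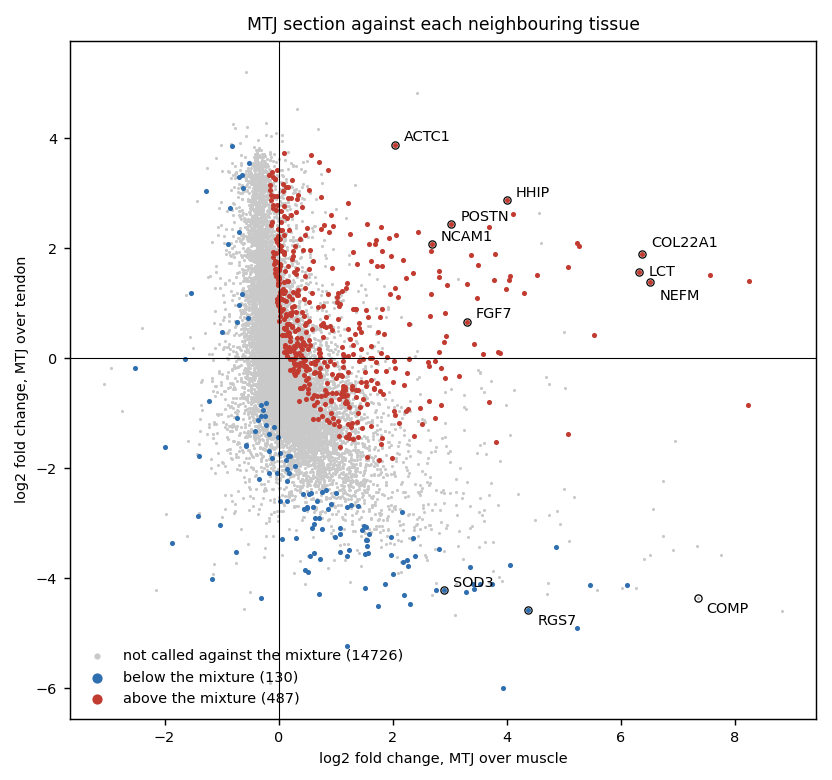
Log2 fold change of each of 15343 genes in the MTJ over muscle (horizontal axis) and over tendon (vertical axis), with the 487 genes above and the 130 genes below the mixture coloured. COL22A1 lies at 6.37 and 1.90, COMP at 7.35 and -4.37.

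Of the 12 MTJ myonuclear markers 8 were above the mixture, 9 adjusted over the list alone, and 0 were below (camera adjusted p = 8.11e-09; adjusted p = 0.480 with an estimated correlation). Beside COL22A1, SORBS2, NCAM1 and TIGD4 (2.50 ± 0.26) these were NAV3 (1.60 ± 0.14), ANKRD1, a stretch-responsive ankyrin repeat protein (0.84 ± 0.11), ADAMTS20 (0.93 ± 0.22) and ITGA7, the laminin-binding integrin of muscle (0.31 ± 0.07). COL24A1 (0.54 ± 0.20), FRAS1 (0.21 ± 0.10), MAML2 (0.08 ± 0.09) and UFSP1 (0.01 ± 0.18) did not pass. The call of ADAMTS20 was lost without horse 14, 18 or 20 (adjusted p = 0.135, 0.133 and 0.145), that of ITGA7 without 17, 18 or 20 (0.0540, 0.0585 and 0.129). With 1 share per horse ANKRD1, ADAMTS20 and ITGA7 had 0.68, 0.78 and 0.15 and were not called (adjusted p = 0.0530, 0.0788 and 0.279). Nor were they with horses 18 and 20 alone (0.0639, 0.152 and 0.0615) or with no filter (0.108, 0.254 and 0.202). ITGA7 was also lost with shares from the lists fixed in advance (0.19, adjusted p = 0.169) and without the horse block (0.231).

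Of 13 macrophage and monocyte markers 8 were above the mixture, and 12 adjusted over the list alone (camera adjusted p = 1.13e-08; adjusted p = 0.480 with an estimated correlation). C1QC, a subunit of complement C1q made by macrophages, was above by 0.78 ± 0.09, LYVE1, a hyaluronan receptor of resident macrophages and lymphatics, by 1.04 ± 0.16, and CSF1R, the receptor for macrophage colony-stimulating factor, by 0.75 ± 0.13. The remaining lists called up were the developmental myosin and myogenic genes (2 of 11 above, 3 alone) and the fibro-adipogenic progenitor markers (3 of 11 above, 8 above and 1 below alone), with adjusted p of 0.00541 and 0.0166, and of 0.480 and 0.847 with an estimated correlation. The 2 developmental genes were ACTC1 and TNNT2, cardiac troponin T (0.66 ± 0.15). The call of TNNT2 was lost without horse 14, 16, 18 or 20 (adjusted p from 0.0607 to 0.142), and without the horse block the adjusted p of ACTC1 was 0.339. With shares from the lists fixed in advance CSF1R and LYVE1 were not called (adjusted p = 0.0676 and 0.0676). With no filter none of C1QC, LYVE1 and CSF1R was called (0.0502, 0.134 and 0.152), and CSF1R was not called with horses 18 and 20 alone (0.0610).

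Lists called down rested on few or no genes. These were the neuromuscular junction (0 of 14 below, 5 alone, and MUSK, the muscle-specific kinase of the endplate, above by 0.88 ± 0.14), oxidative phosphorylation (0 of 28), fibrocartilage (0 of 5), endothelial markers (1 of 15) and ribosomal proteins (0 of 32). Their adjusted p was 0.0495, 0.0373, 0.0166, 0.0166 and 0.0166 with the preset correlation and 0.847, 0.847, 0.847, 0.860 and 0.847 with an estimated correlation. Of the dystrophin-glycoprotein complex, which links fibres to the matrix, 5 of 14 genes were above and 1 below (6 and 1 alone; adjusted p = 0.0686). DMD, dystrophin, was above by 0.35 ± 0.05 and SGCB, beta-sarcoglycan, by 0.40 ± 0.06. DMD was not called with 1 share per horse (0.17, adjusted p = 0.104). Neither gene was called with horses 18 and 20 alone (adjusted p = 0.0542 and 0.0710) or with no filter (0.0502 and 0.119). Of 26 integrin adhesion genes 3 were above (4 alone; adjusted p = 0.528), among them ITGB1, the common beta integrin chain, at 0.36 ± 0.05, which was not called with shares from the lists fixed in advance (adjusted p = 0.134). Schwann cell and nerve markers had 1 of 12 above, NCAM1, and a median log2 ratio of -0.15 (adjusted p = 0.769).

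**Figure D5:**
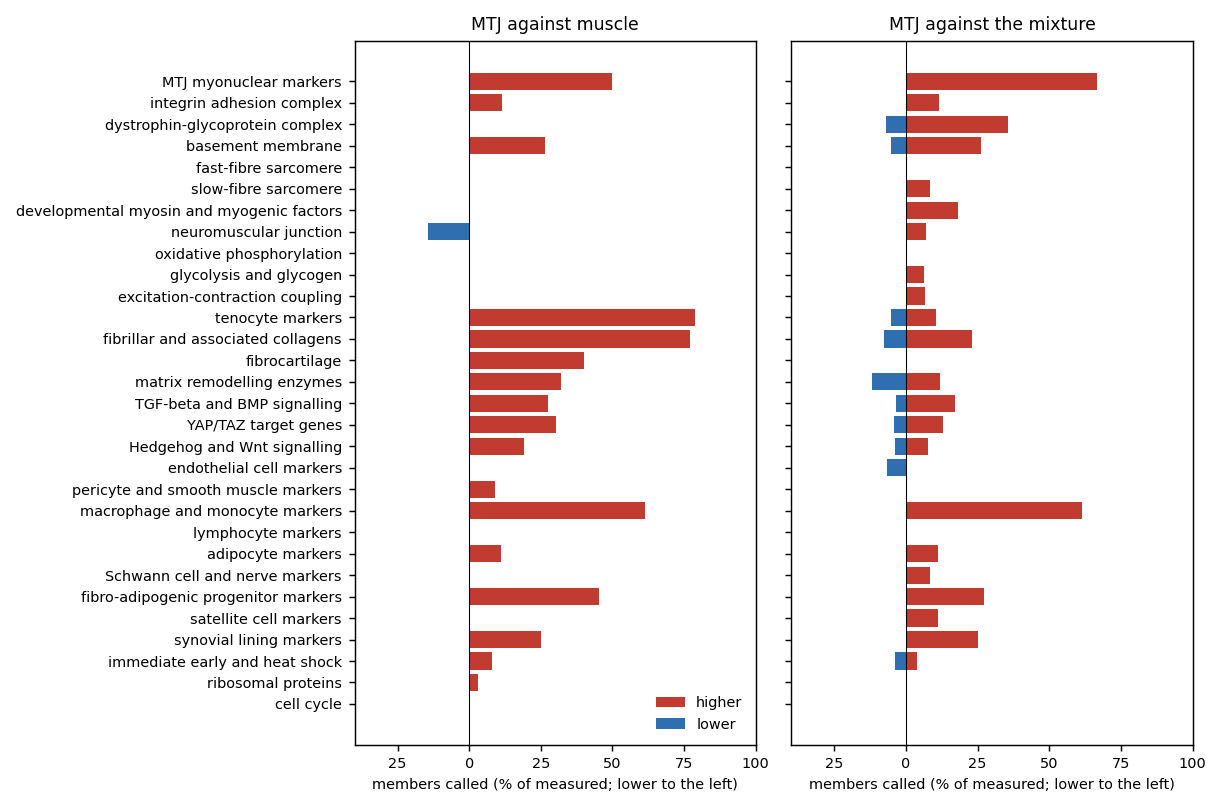
Percentage of measured members of each of 30 gene lists that were called higher (right) or lower (left) in the MTJ against muscle and against the mixture (adjusted p under 0.05 over all genes). Macrophage and monocyte markers had 8 of 13 members called higher in both panels, and MTJ myonuclear markers 6 and 8 of 12.

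The number of genes called against the mixture moved with how the mixture was set. With shares from the lists fixed in advance 198 genes were above and 1053 below, and 325 of the 617 calls were kept. With no filter on low counts 53 and 11 passed and 64 of the 617 calls were kept, among them COL22A1 and FGF7 but not LCT (adjusted p = 0.0502), POSTN (0.0674) or NCAM1 (0.0502). Without the horse block 274 and 102 passed. Without the tendon libraries of horses 14, 16 and 17 only horses 18 and 20 could be compared with their mixture, and there were 178 above and 41 below. Calls lost in that setting can come from the smaller number of horses. Solving both shares together, a setting added after the simulation, gave 1584 and 93. Leaving out horse 14 gave 312 above and 89 below, horse 16 326 and 75, horse 17 562 and 116, horse 18 331 and 124, and horse 20 208 and 61. On simulated counts in which only the macrophage list had been changed, camera against the mixture also called 4 of 29 other lists. With shares solved jointly it called 0 of 29. On the real counts 8 of the 9 lists called against the mixture kept their call with shares solved jointly.

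The authors' deposited table of MTJ changes lists 7613 genes, of which 30 have an adjusted p under 0.05 and 46 a log2 change of at least 1. In the authors' deposited table those 30 genes include 23 that were called above the mixture here, and of the 46 genes 42. Both sets of values come from the same libraries, so the overlap is not independent evidence. In the authors' deposited table the log2 change of COL22A1 is 4.10 and that of FGF7 2.52. The authors' deposited table gives NEFM 4.03 and LCT 3.91, with adjusted p of 0.0639 for both.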

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

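Tests of the explanations below were all chosen after the patterns were seen, whereas the counts of other groupings were planned. Of 237 groups of 5 values examined, 10 (4.22%) held a value far from the other 4, and chance alone marks about 1 in 20 groups. They are given as values. In muscle the share of counts in ribosomal RNA genes was 0.107% in horse 14 and 0.0296 to 0.0329% in the others. PI16, a fibroblast progenitor marker, had a log2 difference between muscle and tendon of -3.32 in horse 14 (others -2.08 to -1.94), and FBLN1, a matrix fibulin, -4.51 in horse 17 (others -6.39 to -6.00). ADAMTS20 had 3.11 in horse 18 (others 0.754 to 1.34) and ITGA7 3.60 (others 1.00 to 1.66). Between MTJ and tendon ITGA7 had 3.46 in horse 18 (others 0.983 to 1.60), and EMILIN1 -2.39 in horse 17 (others -5.31 to -4.53). Between MTJ and muscle GPC4 had -1.87 in horse 17 (others -0.860 to -0.463) and ME1 1.22 in horse 16 (others 0.910 to 0.978). The ratio of FLT1, an endothelial receptor, to the mixture was -0.00785 in horse 18 on the log2 scale (others -0.514 to -0.386). No biological explanation was tested for these 10 values.

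A set of 487 genes lay above the mixture of muscle and tendon. The choice of pseudocount is argued against as the cause of most of them, since 467 were still called with a pseudocount of 2 CPM. Low counts as such are not settled by this, since with no filter on low counts 53 genes were called above. Nerve in the MTJ section cannot be told apart from other causes, since the median log2 ratio of the Schwann cell markers averaged -0.191 ± 0.572 over the horses (SE, n = 5), a spread too wide to decide. Shares set too low cannot be settled by the lists fixed in advance, which put the tendon share at 25.8% and kept 195 of the 487 calls. Muscle's own part of the tendon genes was left out there, and the collagens used had a median log2 change of only -2.41 between muscle and tendon. This raises that share. Shares solved jointly were lower than the main ones, at 76.5 and 12.3%, and gave 1584 genes above. In the simulation the main shares came out at 0.843 and 0.191 where 0.8 and 0.15 were set. Neither of these results points to shares set too low. Transcripts of the junction itself stay open as a hypothesis.

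Muscle transcripts stood at very different levels in the 5 tendon sections. Scaling between libraries is argued against, as the highest over the lowest level was 43.9-fold in CPM without scaling factors. A swap of tendon and MTJ sections within a horse is argued against by the tendon reference genes, whose median was at least 3.82-fold higher in tendon than in MTJ in each of the 5 horses. The 5 tendon sections had the same rank by the muscle reference genes and by 14 other muscle genes, which is consistent with muscle tissue in the tendon sections of horses 14, 16 and 17. A difference between horses in how muscle and tendon meet was not tested.

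CHRNE, ETV4 and MAP2K1 were lower in the MTJ section than in muscle. All 3 genes lay more than 2 standard errors below -0.37, the log2 of the mean muscle share in the MTJ section. They had been picked as the largest falls, so this could hardly come out otherwise. The test therefore cannot decide on less muscle RNA in the MTJ section as a cause. More nerve in the muscle sections cannot be told apart from other causes: the median Schwann cell marker was higher in muscle than in MTJ in 4 of 5 horses, too few to decide. A difference in endplates between the sections stays open as a biological hypothesis and was not tested.

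Other groupings of the libraries were counted for each count of genes. For muscle against tendon 10418 genes were called with the 10 libraries of the 2 tissues, 1 of 100 groupings gave as many, and the highest other gave 0. For MTJ against muscle the count was 2938, 1 of 100 gave as many and the highest other gave 9, and for MTJ against tendon 9800, 1 of 100 and 0. Libraries are paired by horse, and most of the 100 groupings put both libraries of a horse in 1 group, unlike the real one. The real grouping is thus to be set against the 12 that part the libraries of every horse, of which 1 gave as many in each comparison and the highest other gave 0, and 12 are too few for a share under 0.05. For genes outside both tissues the count was 0, which 100 of 100 groupings must reach, so this comparison is void and says nothing about chance. Against the mixture 617 genes were called, 1 of 16 sign changes gave as many and the highest other gave 1, and 16 are too few as well. For gene lists, 17 of 100 groupings gave as many as the real 17 in muscle against tendon (highest other 19), 7 of 100 as many as 17 in MTJ against muscle (highest other 18), and 75 of 100 as many as 12 in MTJ against tendon (highest other 21). The median of the other groupings was 15, 12 and 14 lists, above the real count in MTJ against tendon. Of the 12 that part every horse 2, 3 and 10 gave as many (highest other 19, 17 and 18), and 12 are again too few for a share under 0.05. Against the mixture 2 of 16 sign changes gave as many lists as the real 9 (highest other 9, median of the others 6), too few likewise. The number of lists called with the preset correlation thus did not set the real grouping apart.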

How the results depend on the processing

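Settings without 3 tendon libraries and with shares solved jointly were chosen after seeing the data or the simulation, and the others were planned. Against the mixture the former kept horses 18 and 20 alone. Of the named genes 57 of 57 were called between muscle and tendon, 54 in every alternative, and 47 of 51 between MTJ and muscle, 27 in every alternative. Between MTJ and tendon these numbers were 45 of 48 and 39, and against the mixture 58 of 62 and 13. A left-out horse ended the call of 2, 17, 2 and 19 of them. In the MTJ against muscle the genes lower numbered 137 with RLE size factors (883 higher), 285 with DESeq2 (1155 higher, 80.2% of calls against 91.8%), 46 with no filter and 13 with no replicate block (650 higher). They numbered 623 without the tendon libraries of horses 14, 16 and 17 (1238 higher), and with only the 10 libraries of the 2 tissues 1488 were higher and 1450 lower, in a fit that estimates the spread from other libraries and tests 13564 genes. Changes of at least 2-fold numbered 616 and 11, in muscle against tendon 3303 and 3928, and in MTJ against tendon 2921 and 2972. With each horse left out, calls were 576 to 741 higher and 18 to 40 lower in MTJ against muscle, 5032 to 5141 and 5494 to 5640 in muscle against tendon, and 4656 to 4846 and 4661 to 5015 in MTJ against tendon.

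Outside both tissues DESeq2 called 3 genes above, leaving out a horse gave 0 to 1 above and 0 to 1 below, and leaving out the 3 tendon libraries gave 1 above (FGF7, adjusted p = 0.0397). Against the mixture 53 and 11 genes passed with no filter, 198 and 1053 with shares from lists fixed in advance, and 464 and 391 with 1 share per horse. With reference genes left out 489 and 65 passed, with no replicate block 274 and 102, and with horses 18 and 20 alone 178 and 41. Shares solved jointly gave 1584 and 93, and a 2-fold threshold gave 103 and 29. An edgeR test that needs both tissues gave 0 and 0. Leaving out a horse gave 208 to 562 above and 61 to 124 below. The tendon share was 25.8% with lists fixed in advance, and leaving out a horse gave 76.2 to 80.3% for muscle and 13.8 to 16.9% for tendon. Gene lists called numbered 16, 14, 13 and 9 in the 4 comparisons, and 0, 5, 0 and 0 with an estimated correlation. With fry they numbered 21 in MTJ against tendon and 3 against the mixture, and with horses 18 and 20 alone 3 against the mixture. Leaving out a horse gave 16 to 16, 14 to 14, 12 to 16 and 6 to 9. The log2 ratio of UFSP1 to the mixture, 0.01, turned to -0.15 with lists fixed in advance and -0.072 with 1 share per horse. It ran from -0.12 (without horse 17) to 0.080 with a horse left out, and was -0.044 with horses 18 and 20 alone. The log2 ratio of MAML2 to the mixture, 0.08, turned to -0.34 with lists fixed in advance. The cause was not tested. RLE size factors, the 1 other scaling run, moved the median of all genes by at most 0.0351 in size on the log2 scale in the 3 comparisons between tissues.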

Other observations

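The observations below were chosen after the values were seen. Over 11 Schwann cell markers the median log2 ratio of the MTJ section to the mixture was -0.903, -0.594, -1.35, 1.93 and -0.0485 in horses 14, 16, 17, 18 and 20.

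The 3 genes that DESeq2 called above both tissues differ in what is known of them. ME1 makes cytosolic NADPH from malate, CD52 is carried by leukocytes, and HHIP binds Hedgehog ligands. Against the mixture their log2 ratios were 1.08 ± 0.12, 1.43 ± 0.12 and 2.46 ± 0.44 (SE, n = 5, limma adjusted p = 0.000157, 1.66e-05 and 0.0306), and each was above 0 in 5 of 5 horses. Without horse 14 the adjusted p of HHIP was 0.130, without horse 16 0.0693 and without horse 20 0.0605. A pseudocount of 2 CPM lowered its ratio to 1.41 (adjusted p = 0.107), and its adjusted p was 0.141 with no filter and 0.136 with horses 18 and 20 alone.

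CAT, the peroxide-degrading catalase, took the largest share of counts in the tendon libraries of horses 18 and 20, at 3.51 and 4.08%. Those are the horses with the least muscle RNA in their tendon sections.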
